A study of Mus musculus with 9 samples.

How the data were processed

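RNA from B16 melanoma tissue of C57/Bl6 mice was measured on 9 single-colour Illumina BeadChip arrays, 5 from the PBS group and 4 from the PC61 group. Per the labels, the mice were 8 weeks old and the tissue was taken at day 14 after inoculation. Per the labels' protocols, RNA was isolated with Trizol and RNeasy, and biotin-labelled cRNA was made with the Ambion MessageAmp kit. The scanner, the export software and any background handling are not given in the sources used here. Group and replicate number came from the sample labels. Nothing in them says that the replicates are separate mice beyond a replicate number, so p-values measure the spread between these samples.

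The deposited raw table gave an intensity on a linear scale for 45273 probes, with a detection p-value for each probe and array per the file headers. The lowest intensity was the same on each array, as if the export had been offset to keep values above 0. Raw medians ran from 21.5 on PC61 replicate 4 to 41.6 on PBS replicate 1. The authors' second table held quantile-normalized intensities of 17382 probes. Recomputing quantile normalization over all probes from the raw table gave these values to within 0.0514%. The probes in it were those with a detection p under 0.01 on at least 4 PBS or at least 3 PC61 arrays, a rule found by comparison with the raw table, for which 0 probes differed. The same table gave the authors' ratio of PC61 to PBS group means, a test statistic, a p-value and a Benjamini-Hochberg value per the file headers. The test is not given in the sources used here. Recomputed limma statistics on log2 of the authors' values differed from the deposited statistic by at most 5.4e-14. The value table of the series held the authors' normalized intensities again, with a largest difference of 0, so its scale is linear and no centring was applied.

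The values reported here start from the raw table. A detection p outside the range from 0 to 1 removed 3 probes, which left 45270. Background was corrected with normexp using the detection p-values, an offset of 16 was added, and arrays were quantile normalized on the log2 scale with the neqc function of limma 3.58.1 in R 4.3.3. Normexp and an offset shrink the fold changes of dim probes. Quantile normalization gives all arrays the same distribution, so a shift of most genes in one direction cannot be seen. Probes with a detection p under 0.05 on at least 4 arrays were kept, 20190 in all. Between 18572 probes on PBS replicate 4 and 20742 on PC61 replicate 4 were detected. The number of arrays limits the precision.

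Gene names came from the platform annotation supplied for the probes of the authors' table, with symbols updated by gene identifier through a RefSeq gene table. Of the authors' probes, 14942 had 1 symbol, 8 had several and 2432 had none here. The reference held the gene identifier of 14927 of the 14942, and the other 15 kept the annotation's symbol. Of the detected probes, 14906 had 1 symbol and 5284 did not, and the latter are not named. Il2ra, the gene of the CD25 protein that the PC61 antibody binds, is unnamed among these probes and was not analysed here. The same holds for Cd4, Cd8a, Gzma, Mki67 and Cd68. No coordinates are given because no genome build is named in the sources used here. Where a gene had several detected probes (3516 genes), the probe with the highest mean over all arrays stood for it. In a test of single probes, 5 genes had probes past the threshold in both directions.

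The groups were compared with lmFit and eBayes of limma at default settings, two-sided, over 10096 genes. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called higher or lower. Errors of single values are SD over replicates, and errors of log2 fold changes are the standard errors of limma. The 31 gene lists, the tests and the rule for named genes were fixed before the data were examined. Lists with at least 3 measured genes were tested with camera at a preset correlation of 0.01, adjusted over 30 lists, and with camera at an estimated correlation and with fry. Named genes were Foxp3, the 10 genes with the largest log2 fold change in each direction among called genes whose groups did not overlap, and up to 3 members with the smallest unadjusted p of each list that passed camera. The same number came from the regulatory T cell, pan T cell, cytotoxic lymphocyte, interferon gamma response and melanocyte lists whatever their result. Other list members were named as examples after their values were seen. The Foxp3 difference was tested with an exact two-sided permutation test over 126 splits of the 9 samples.

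The procedure was tested on simulated arrays with the means and spreads of these 10096 genes. With no change, 0 genes were called. For 50 changed genes at each size, 6% were recovered at a log2 change of 0.585, 48% at 1, 88% at 2 and 98% at 3, and 8 unchanged genes were called beside 200 changed ones. The simulated arrays were independent and carried no axis of variation shared by many genes, which the real arrays do.

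Alternatives covered background correction, normalization, the authors' values as a start, the filter on dim probes, the rule for several probes, the variance model, array weights, a replicate block, each sample left out in turn, other thresholds and other set tests. A block for the slide was not run because no slide is given in the sources used here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.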

Results

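Gene expression was measured in B16 tumours, a transplantable mouse melanoma, at day 14 after inoculation into C57/Bl6 mice. The 4 samples labelled PC61, an antibody against CD25 that is used to deplete regulatory T cells, were set against 5 labelled PBS. The comparison asks how the tumour tissue of mice treated with the antibody differs from that of controls. Each array detected between 18572 and 20742 probes, and 10096 genes were tested.

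Foxp3, the transcription factor of regulatory T cells, had a log2 intensity of 9.05 ± 0.24 (SD, n = 5) in PBS and 8.73 ± 0.18 (SD, n = 4) in PC61. The difference of -0.32 was not past the threshold in an exact two-sided permutation test (p = 0.0794, with 0.00794 the smallest p the design allows). In the same exact permutation test it was -0.19 (p = 0.167) with cyclic loess and -0.37 (p = 0.0397), past the threshold, with 75th percentile scaling. The limma adjusted p was 0.203, and 0.0466 with array weights. On PC61 replicate 4, which had the lowest pan T cell list mean (-1.02 relative to the PBS mean), Foxp3 was at 8.886, its highest PC61 value. Whether this probe follows the T cell content of a sample was not tested. Of the 18 genes of the regulatory T cell list 7 were measured, with a median of 0.38 (camera adjusted p = 0.381). The median was 0.23 without PC61 replicate 1, 0.25 without PBS replicate 5 and 0.24 with a normexp offset of 50. Of the 7 measured genes 1 rose, Tnfrsf18, the GITR receptor, by 1.02 ± 0.28 (SE, adjusted p = 0.0261). This call was lost when PBS replicate 4, PBS replicate 5, PC61 replicate 3 or PC61 replicate 4 was left out, with the adjusted p at 0.0592, 0.0628, 0.0788 and 0.0539. Tnfrsf18 was highest on PC61 replicate 4 (8.175), the array with the lowest pan T cell and the highest keratinocyte list mean (2.615 relative to the PBS mean). The values of Tnfrsf4 (OX40) and Itgae (CD103) were 0.57 ± 0.23 (adjusted p = 0.0819) and 0.47 ± 0.21 (adjusted p = 0.118).

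Across the tissue, 2679 genes (26.5%) were called, of which 1552 were higher and 1127 lower in PC61. At least 2-fold changes were found in 1094 of the higher and 414 of the lower genes. At an unadjusted p under 0.05 there were 4215 genes, and the smallest adjusted p was 0.0122. The groups did not overlap in 2142 genes (21.2%), where chance gives 1.59%. The authors' deposited table held 4106 of 17382 probes past its own Benjamini-Hochberg value of 0.05, of which 2209 were higher in PC61. The count depended on single arrays. It was 753 without PC61 replicate 3, 1345 without PBS replicate 5, 1443 without PBS replicate 4, 1706 without PBS replicate 2 and 1740 without PC61 replicate 1.

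The genes that rose most included several known from skin and muscle. Tgm3, a transglutaminase of epidermis and hair, rose 6.51-fold (2.70 ± 0.52, SE, log2, adjusted p = 0.0122). Sfn, the keratinocyte 14-3-3 sigma protein, rose 5.75-fold, and Dlx3, a homeobox factor of skin and hair follicle, rose 5.84-fold. Ky, a muscle protein, rose 6.45-fold (adjusted p = 0.0122) and was detected on 2 of the 5 PBS arrays and on all 4 PC61 arrays, so its fold is limited by background. The others were Syndig1l (7.67-fold), Tro (7.63-fold), Stra6, a retinol transporter (6.71-fold), Gp9, a platelet glycoprotein (6.60-fold), and Bmp4, a secreted growth factor (5.79-fold). Tgm3, Stra6 and Bmp4 were detected on 4 of the 5 PBS arrays, so background limits their folds in part too. Krtap4-13, a hair keratin-associated gene, was 6.47-fold higher, but it belongs to a multigene family whose members one probe can fail to separate, so its identity is uncertain. Its adjusted p was 0.0647 without PC61 replicate 3.

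Among the genes that fell most, Sox11, a transcription factor, was 6.83-fold lower in PC61 (-2.77 ± 0.81, SE, log2, adjusted p = 0.0303). Car9, the hypoxia-inducible carbonic anhydrase IX, was 6.77-fold lower (-2.76 ± 0.69, adjusted p = 0.0193), and Epha3, an ephrin receptor, was 6.70-fold lower (adjusted p = 0.0193). Unc5c, a netrin receptor (6.28-fold), Prdm16 (6.10-fold), Dnaic1 (5.52-fold), Dmrta2 (5.49-fold), Hap1 (4.99-fold), Espn, an actin-bundling protein (4.96-fold), and E330034G19Rik (4.82-fold) were lower as well. Unc5c, Dmrta2 and E330034G19Rik were detected on 3 of the 4 PC61 arrays. PC61 replicate 4 had the lowest value of all these genes. Without it the difference was -1.70 for Sox11, -1.83 for Car9, -1.67 for Unc5c, -1.34 for Dnaic1, -1.49 for Hap1 and -1.45 for E330034G19Rik. Without PC61 replicate 3, the adjusted p of Sox11 was 0.0737 and that of Epha3 was 0.0516, and only Car9 of the 10 genes passed. The calls of Sox11, Unc5c and Dnaic1 were lost also without PBS replicate 2, 4 or 5 (adjusted p from 0.058 to 0.0882), those of Hap1 without PBS replicate 2 or 5, that of Prdm16 without PBS replicate 5, and those of Dnaic1 and E330034G19Rik without any 1 of the 5 PBS arrays.

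**Figure D1:**
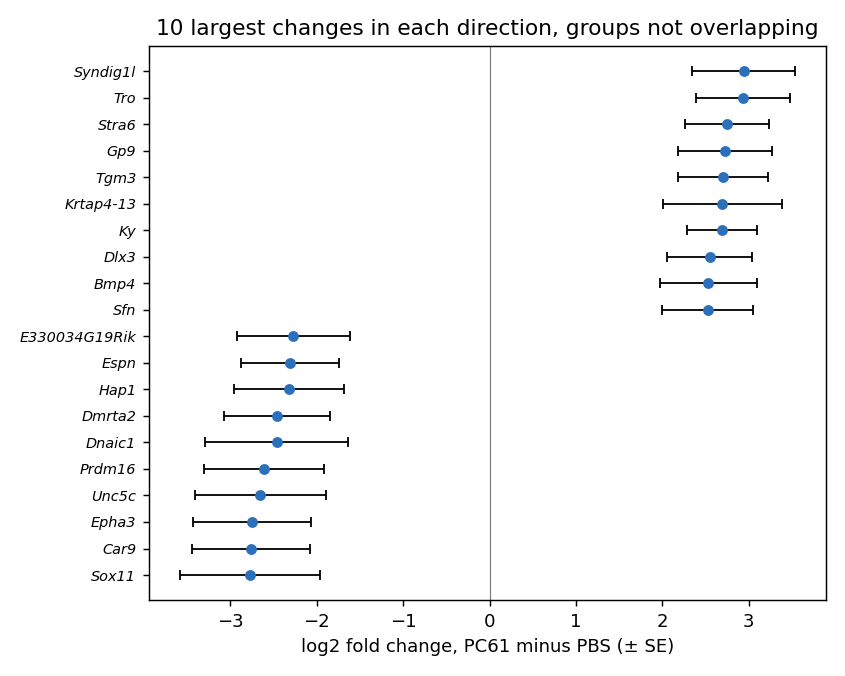
Log2 fold change (PC61 minus PBS, horizontal axis) of the 10 genes with the largest change in each direction among called genes whose groups did not overlap; points are estimates and bars their standard errors (5 PBS and 4 PC61 arrays). The values run from -2.77 for Sox11 to 2.94 for Syndig1l.

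Markers of the tumour cells and of cell division were lower in PC61. The melanocyte and melanoma list had a median of -1.84 over 15 genes (camera adjusted p = 9.94e-05, and adjusted p = 0.557 with an estimated correlation), and 5 of its genes fell, or 14 when adjusted over the list alone. Mitf, the melanocyte transcription factor, was lower by -1.29 ± 0.29 (SE, adjusted p = 0.0154). Tyr, the tyrosinase of melanin synthesis, was lower by -1.99 ± 0.47 (adjusted p = 0.0168), and Mc1r, the melanocortin receptor, by -2.22 ± 0.60 (adjusted p = 0.0235, and -1.46 without PC61 replicate 4). Both genes were detected on 3 of the 4 PC61 arrays. The list mean on PC61 replicate 4 was -4.32 relative to the PBS mean, against -1.58 to -0.32 on the other PC61 arrays. Without that array the list median was -1.03 (adjusted p = 1.44e-05). In the proliferation list 11 of 18 genes fell, or 16 over the list alone (median -0.87, camera adjusted p = 1.83e-06, and adjusted p = 0.557 with an estimated correlation). Rrm2, a subunit of ribonucleotide reductase, fell by 1.68 (adjusted p = 0.0152), and the mitotic genes Bub1b and Tpx2 fell by 0.99 and 0.94. The proliferation list stayed lower with the melanocyte list mean as a covariate (-0.58, camera adjusted p = 0.000467). This pass rests on the preset correlation, and the covariate was chosen after seeing the data. A linear adjustment need not remove a change of tissue share in full, so the remaining fall decides nothing. In the angiogenic factor list 4 of 6 genes fell (median -1.13, camera adjusted p = 0.0239, and adjusted p = 0.557 with an estimated correlation), among them Pgf (-1.50 ± 0.29), Vegfb (-1.61 ± 0.40) and Vegfc (-0.98 ± 0.24). The call of this list was lost over genes detected on all 9 arrays at a detection p under 0.01 (adjusted p = 0.0981) or under 0.05 (adjusted p = 0.105), and with the melanocyte list mean as a covariate (-0.45, adjusted p = 0.0928). Pgf was detected on 3 of the 4 PC61 arrays.

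Markers of tissues that surround a tumour under the skin were higher in PC61. All 13 measured skeletal muscle genes rose (median 2.09, camera adjusted p = 7.59e-09, and adjusted p = 0.557 with an estimated correlation). Ckm, muscle creatine kinase, rose 5.62-fold (2.49 ± 0.34, SE, adjusted p = 0.0122), Actn3 rose 4.33-fold and Pvalb rose 4.26-fold. In the keratinocyte list 8 of 11 genes rose, or 10 over the list alone (median 1.80, camera adjusted p = 9.94e-05, and adjusted p = 0.557 with an estimated correlation). Krt5, a basal keratin, rose 5.29-fold (adjusted p = 0.0166) and Lgals7 rose 3.47-fold (adjusted p = 0.0204). The adipocyte list had a median of 1.28 over 6 genes (camera adjusted p = 0.0123, and adjusted p = 0.557 with an estimated correlation). Lep, the leptin gene, was the 1 gene of it past the threshold over all genes tested (1.68 ± 0.44, adjusted p = 0.0224), and 6 were when adjusted over the list alone. The adipocyte call was lost with array weights (0.90, adjusted p = 0.0619).

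Stromal lists shifted the same way. In the fibroblast and matrix list 6 of 19 genes rose and 1 fell (median 0.78, camera adjusted p = 0.00152, and adjusted p = 0.557 with an estimated correlation). Mmp2, a gelatinase, rose by 1.96 ± 0.39 (SE, adjusted p = 0.0124), Fn1, fibronectin, by 1.58 ± 0.42 and Pdgfrb by 1.00 ± 0.25. Timp1, a metalloproteinase inhibitor, was the one that fell (-1.59, adjusted p = 0.0285). In the pericyte and smooth muscle list 5 of 8 genes rose (median 1.11, camera adjusted p = 0.00414, and adjusted p = 0.557 with an estimated correlation), with Notch3 at 1.56 ± 0.34, Myl9 at 1.51 ± 0.28 and Tagln at 0.85 ± 0.19. Tagln was detected on 3 of the 5 PBS arrays. In the mast cell and basophil list 5 of 8 genes rose (median 1.43, camera adjusted p = 0.00347, and adjusted p = 0.557 with an estimated correlation). They included the mast cell proteases Mcpt4 (2.16 ± 0.48) and Tpsb2 (1.65 ± 0.32) and the receptor gene Kit (1.42 ± 0.30), which melanocytes also express. The melanocyte list was lower in the same samples. With its mean as a covariate, the medians were 1.38 for skeletal muscle, 0.64 for keratinocyte, 0.42 for fibroblast and matrix, 0.71 for pericyte and smooth muscle and 0.87 for mast cell and basophil, all still past the threshold. These passes rest on the preset correlation, and the covariate was chosen after seeing the data. A linear adjustment need not remove a change of tissue share in full, so what remains decides nothing.

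**Figure D2:**
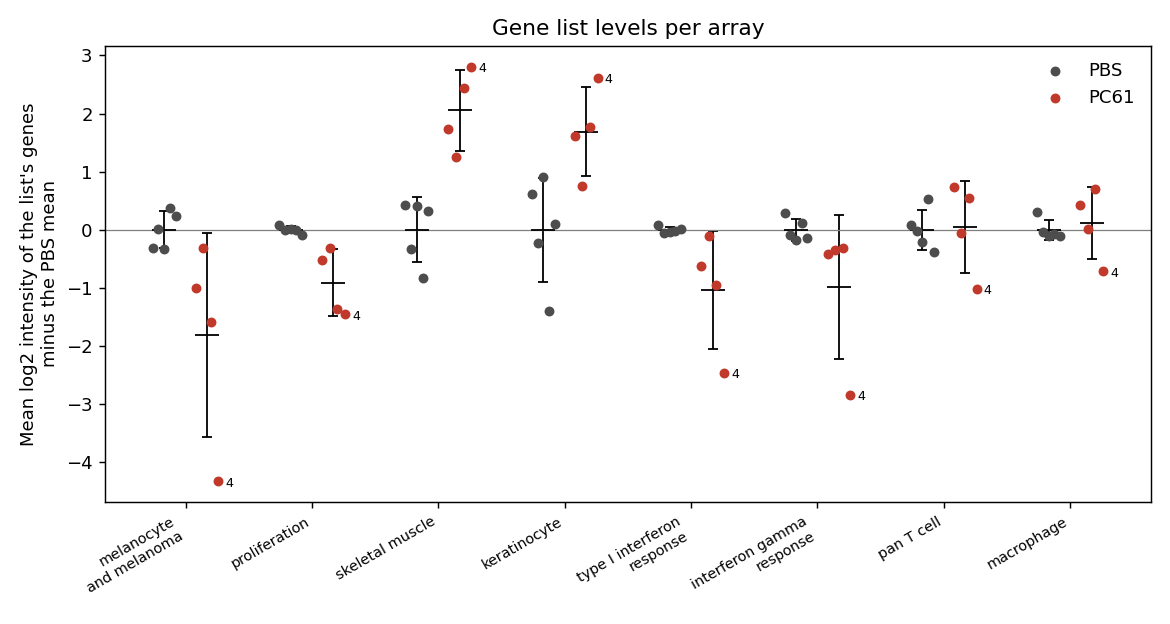
Mean log2 intensity of each list's genes minus the PBS mean (vertical axis) for 8 gene lists; each point is an array (5 PBS in grey, 4 PC61 in red, PC61 replicate 4 marked 4), and the bars are the group mean ± SD. The melanocyte mean of PC61 replicate 4 lies at -4.32 and its interferon gamma response mean at -2.83.

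Both interferon lists had a lower median in PC61, in the samples in which the melanocyte list was lower. In the type I interferon response list 6 of 17 genes fell, or 11 over the list alone (median -1.15, camera adjusted p = 0.000549, and adjusted p = 0.557 with an estimated correlation). Ddx58, the RNA sensor RIG-I, was lower by -0.84 ± 0.20 (SE, adjusted p = 0.0167), and Cmpk2 and Usp18 by -1.46 ± 0.38 and -1.10 ± 0.29. The interferon gamma response list had a median of -1.10 over 19 genes (camera adjusted p = 0.00253, and adjusted p = 0.691 with an estimated correlation). In it Tgtp1, an interferon-induced GTPase, was lower by -1.78 ± 0.49 (adjusted p = 0.0256) and Cd274, the PD-L1 gene, by -1.10 ± 0.37 (adjusted p = 0.0486), and 0 genes passed when adjusted over the list alone. Gbp2 was at -1.15 ± 0.41 (adjusted p = 0.0572). Tgtp1 was detected on 3 of the 4 PC61 arrays. PC61 replicate 4 set much of the size. Without it the medians were -0.66 (adjusted p = 0.00184) and -0.29 (adjusted p = 0.00984). Cd274 was at -0.66 (adjusted p = 0.0666), Tgtp1 at -1.175 (adjusted p = 0.0220) and Gbp2 at -0.63 (adjusted p = 0.05745). With the melanocyte list mean as a covariate neither list passed, at -0.14 (adjusted p = 0.602) for type I and 0.16 (adjusted p = 0.48) for interferon gamma. The call of Cd274 was lost without any 1 of the arrays but PC61 replicate 2.

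Lists of T cells and cytotoxic cells did not pass in the fit of all 9 arrays. Of the listed genes, 9 of 20 were measured for pan T cell, 11 of 21 for cytotoxic lymphocyte and 7 of 19 for NK cell. The pan T cell list had a median of 0.12 over 9 genes (camera adjusted p = 0.879), with 0 genes past the threshold. Cd2, Cd6 and Cd3d were at 0.66 ± 0.33, -0.41 ± 0.44 and -0.46 ± 0.55. The cytotoxic lymphocyte list had a median of -0.08 over 11 genes (adjusted p = 0.915), with Cd8b1, Cst7 and Prf1, the perforin gene, at -0.25 ± 0.16, 0.41 ± 0.32 and -0.21 ± 0.21. On PC61 replicate 4 the log2 intensity was 10.23 for Cd8b1 and 5.169 for Cd3d, the lowest of Cd3d, so Cd8b1 did not follow Cd3d there. The NK cell list (median 0.00) and the immune checkpoint list (0.12) had an adjusted p of 0.915 as well. Without PC61 replicate 4, Cd2 was higher by 0.93 (adjusted p = 0.0458), Cd6 and Cd3d were at 0.11 and 0.21, and the medians were 0.47 for pan T cell (adjusted p = 0.0723), 0.43 for cytotoxic lymphocyte (adjusted p = 0.122) and 0.30 for NK cell (adjusted p = 0.351). Without PC61 replicate 3 these medians were 0.00, -0.26 and -0.26, and none passed. The pan T cell list passed as higher with array weights (0.61, adjusted p = 0.0226). It passed also without PC61 replicate 4 and PBS replicate 4 together (0.59, adjusted p = 0.0109) and with the melanocyte covariate (0.71, adjusted p = 0.0113). With that covariate cytotoxic lymphocyte passed too (0.67, adjusted p = 0.0257). The covariate and the joint removal were chosen after seeing the data. PC61 replicate 4 had the lowest pan T cell mean (-1.02 relative to the PBS mean), so these passes are not separate support. They rest on the preset correlation. Over all 9 arrays both lists had an adjusted p of 0.953 with an estimated one.

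Other immune and vascular lists did not pass camera in the fit of all 9 arrays. Their medians were 0.09 for macrophage, 0.72 for alternative macrophage activation, 0.03 for dendritic cell, 0.34 for neutrophil, 0.85 for plasma cell, 0.29 for eosinophil and type 2, 0.31 for MHC class II presentation and -0.43 for MHC class I presentation. They were -0.59 for chemokine, 0.94 for high endothelial venule and lymphoid tissue, -0.02 for blood endothelium, 0.84 for lymphatic endothelium, -0.63 for hypoxia and glycolysis and -0.17 for erythroid. Adjusted p-values of these 14 lists ran from 0.0615 (plasma cell) to 0.915. With fry, plasma cell (adjusted p = 0.000592) and hypoxia and glycolysis (adjusted p = 0.0348) passed. Of the 11 plasma cell genes only 4 were measured. Sdc1 (1.82) and Xbp1 (0.60) were called, and Mzb1 (limma adjusted p = 0.116) and Irf4 (limma adjusted p = 0.449) were not. Within the 14 lists some genes were called, such as Apoe (1.23, adjusted p = 0.0204). The called chemokine genes were Cxcl14 (1.96), Cxcl12 (1.37) and Ccl2 (-1.07, adjusted p = 0.042). Slc2a1, a glucose transporter, was called at -0.99 and Egln3 at 1.72. The list median and the camera direction had opposite signs for blood endothelium, erythroid and NK cell, and median and mean had opposite signs for dendritic cell (0.03 and -0.13), NK cell (0.00 and -0.09) and erythroid (-0.17 and 0.18). Without PC61 replicate 4, MHC class II (0.59, adjusted p = 0.00772), macrophage (0.47, adjusted p = 0.0259), neutrophil (0.66, adjusted p = 0.034) and plasma cell (1.00, adjusted p = 0.034) passed as higher. Without PC61 replicate 3 the medians were 0.09 for MHC class II, -0.07 for macrophage, 0.14 for neutrophil and 0.09 for eosinophil and type 2, and none of these passed. Among lists that did not pass without PC61 replicate 4, the medians without that array were 0.19 for chemokine, 0.33 for lymphatic endothelium and -0.20 for MHC class I presentation. Plasma cell passed also without PBS replicate 2 (0.99, adjusted p = 0.0401), PBS replicate 4 (0.79, adjusted p = 0.0471) or PC61 replicate 1 (0.94, adjusted p = 0.0487), and alternative macrophage activation without PBS replicate 1 (0.87, adjusted p = 0.0269). Over genes with a detection p under 0.01 on all 9 arrays, alternative macrophage activation (0.82, adjusted p = 0.0149) and plasma cell (0.60, adjusted p = 0.04997) passed as higher too. With the melanocyte covariate MHC class II (0.67), macrophage (0.45), neutrophil (0.75), plasma cell (0.74) and chemokine (0.49) passed as higher, and with array weights MHC class II (0.52) did. Only 2 of the 16 genes of the B cell list were measured, Blnk (1.01) and Cd37 (0.69), so it was not tested.

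**Figure D3:**
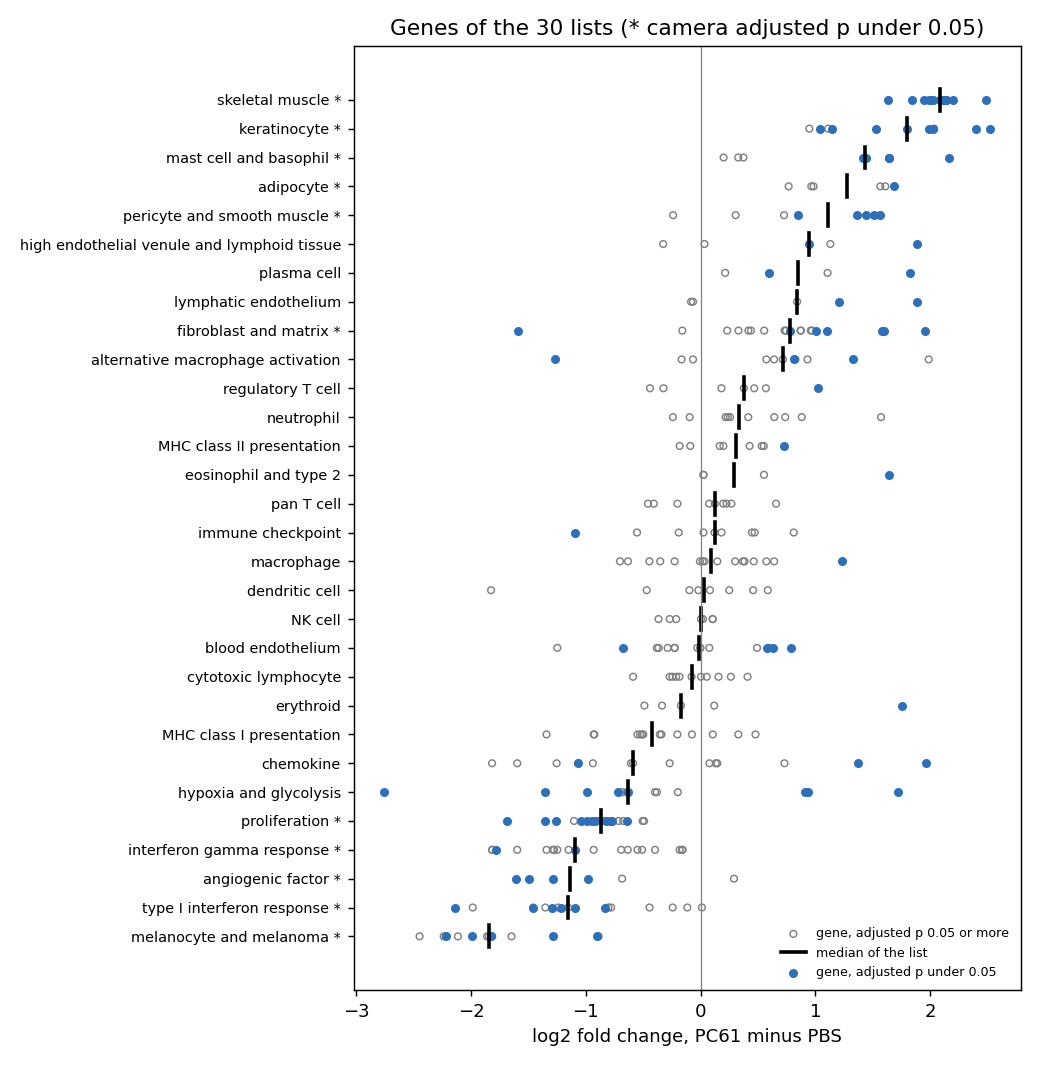
Log2 fold change (PC61 minus PBS, horizontal axis) of each measured gene of the 30 tested lists; filled points are genes with an adjusted p under 0.05, open points the others, black bars the list medians, and stars the 11 lists past camera. Medians run from -1.84 for melanocyte and melanoma to 2.09 for skeletal muscle.

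Of the 30 lists 11 passed camera, 6 higher and 5 lower. With the correlation estimated per list 0 passed (0 also at an unadjusted p under 0.05), and with fry, which asks whether a list's genes move one way, 6 passed, 4 of them among the 11. The other lists past camera did not pass fry. Their fry adjusted p was 0.101 for melanocyte and melanoma, 0.107 for type I interferon and 0.242 for interferon gamma response. It was 0.0741 for keratinocyte, 0.0885 for both fibroblast and matrix and adipocyte, and 0.0734 for angiogenic factor. Without PC61 replicate 3, the adjusted p of Mitf, Tyr, Mc1r, Rrm2, Bub1b, Vegfb, Vegfc, Krt5, Lgals7, Lep, Fn1, Pdgfrb, Cmpk2, Usp18 and Tgtp1 lay between 0.0501 and 0.0724. Without PBS replicate 4 or 5, the calls of Lep and Tgtp1 were lost (adjusted p from 0.0503 to 0.0582), as were those of Mc1r without PBS replicate 4, of Fn1, Cmpk2 and Usp18 without PBS replicate 5, and of Pdgfrb without PC61 replicate 1. The first principal component held 67.2% of the variance and ran from -66.3 on PBS replicate 4 to 93.7 on PC61 replicate 4, with all PBS arrays below all PC61 arrays.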

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

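What each explanation in this part would show was written after the results had been seen, except for the count of regrouped samples. The fits without PC61 replicate 4, the other normalizations and the estimated correlation were planned, and the tests with the melanocyte covariate, of the relation within groups and of detected genes were chosen afterwards. In 192 comparisons of a sample with the rest of its group, 9 samples lay far out, and chance gives 9.6. PC61 replicate 4 was the far sample in 5 of the 9. It was low in the interferon gamma response list (gap over range 0.9623; -2.83 against -0.42 to -0.32), the chemokine list (0.8669; -1.94 against 0.12 to 0.43) and the dendritic cell list (0.8584; -0.96 against 0.08 to 0.25). It was low also for Car9 (0.8435; 4.88 against 8.30 to 8.93) and Gbp2 (0.9126; 9.16 against 11.1 to 11.3). PBS replicate 1 was high in the macrophage list (0.8286), PC61 replicate 1 was high for Tgm3 (0.8717), PBS replicate 4 was low for Kit (0.8267) and PC61 replicate 3 was high for Prf1 (0.9263). Among the detected probes without a single gene name, which the comparison of genes does not use, 557 passed the threshold, 257 higher and 300 lower in PC61.

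The regroupings argue against chance as the source of the 2679 called genes, only as far as 100 splits allow. The first principal component held 67.2% of the variance, so the called genes are not separate results. Of 100 splits of the 9 arrays into groups of the same sizes, 1 gave as many genes, the real one. The highest of the others gave 1105, and it set PBS replicates 1, 2, 4 and 5 against PBS replicate 3 with the 4 PC61 arrays. The next highest gave 0.

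The first pattern is the rise of muscle, keratinocyte and fat genes beside the fall of melanocyte genes. Normalization is argued against as its cause: over 5 normalizations, the smallest median shift among the melanocyte, muscle and keratinocyte lists was 1.658 in the same direction. A change inside the tumour cells alone is argued against by the median rise of 1.968 in muscle, keratinocyte and fat genes. This holds only if B16 cells do not make them, a premise not tested here. The rise is part of the pattern itself and was known beforehand, so it is no separate test. A fall of melanocyte genes per tumour cell stays open. The 1 relation computed goes with more surrounding tissue in the PC61 pieces. Within groups, arrays with less melanocyte signal had more keratinocyte and muscle signal (r = -0.7226, exact permutation p = 0.00451, rho = -0.833 with p = 0.00799, n = 9). Without PC61 replicates 4 and 2, r was -0.607. The first principal component held 67.2% of the variance. Any cause that moves arrays along it could give such a relation, so the relation does not single out surrounding tissue. With the melanocyte list mean as a covariate the muscle (1.384), fat (0.9496) and keratinocyte (0.6398) lists still passed. These passes rest on the preset correlation. With an estimated one, none of these lists passed over all 9 arrays without the covariate (adjusted p = 0.557). A linear adjustment for a log2 list mean need not remove a change of tissue share in full, so what remains decides nothing. Whether the PC61 pieces held more surrounding tissue stays open. So does its source, smaller tumours or how the pieces were cut, since no tumour size was analysed.

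The second pattern is the fall of the interferon lists. PC61 replicate 4 alone is argued against as its cause, since without it the type I list still passed at -0.6559 and the interferon gamma list at -0.2936, and in both lists the means of the other 3 PC61 arrays lay below those of all 5 PBS arrays (-0.11 at most against -0.05 at least, and -0.32 against -0.17). These passes rest on the preset correlation; over all 9 arrays neither list passed with an estimated one (adjusted p = 0.557 and 0.691). With the melanocyte list mean as a covariate the medians were -0.142 (from -1.15) and 0.1571 (from -1.10) and neither list passed, which is consistent with a lower share of tumour tissue. That covariate differs between the groups, so part of a treatment effect could be removed with it. An effect of the treatment on interferon signalling stays open, as untested.

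The third pattern is that PC61 replicate 4 stands apart. A failed hybridization or poor RNA stays open: 20742 probes were detected, the most of any array (20506 at most on the others), but its raw mean (184), raw median (21.5) and median correlation with its own group (0.902) were the lowest, and RNA quality was not analysed. A piece with little tumour tissue was tested by the number of melanocyte genes detected, which was 12 of 15, against 15 on each other array. Under the bound first set for this test, a count that high argued against the explanation. The count is now read as deciding nothing, a change made after it was seen, because bright markers stay detected after a large fall. The list mean of -4.32, the lowest of the 9 arrays, goes with little tumour tissue but was known before and is no independent test, and the explanation stays open.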

How the results depend on the processing

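2 alternatives were chosen after seeing the data: leaving out PC61 replicate 4 and PBS replicate 4 together, and the melanocyte list mean as a covariate. Against 2679 genes (1552 higher, 1127 lower) and 11 lists (6 higher, 5 lower), background correction, normalization, the authors' values, no filter, a detection p under 0.01 on 4 arrays, the rule for several probes, single probes and the variance model gave 2570 to 2954 genes and the same 11 lists where lists were run. The fit with no filter tested 10119 genes, since only probes of the authors' filtered table have names here. It therefore hardly tests the effect of filtering. Cyclic loess moved the share of higher calls from 57.9% to 68.1% and the median of all genes by 0.107. Array weights gave 4497 genes (2225 lower), ended the adipocyte call (0.90) and brought in pan T cell (0.61) and MHC class II (0.52, adjusted p = 0.0343). A detection p under 0.01 on all 9 arrays, which drops genes undetected in part of either group, gave 1919 genes (978 higher, 941 lower) with 8 lists higher, ended the angiogenic factor call and brought in alternative macrophage activation (0.82) and plasma cell (0.60). Stricter or looser thresholds gave 1508 genes (414 lower) at 2-fold, 1810 lower genes at an adjusted p under 0.1, and 4215 genes (2024 lower) unadjusted.

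With a replicate block in limma, 0 genes passed (0 higher, 0 lower; 3049 at an unadjusted p under 0.05) and 12 lists did, with plasma cell (0.82, adjusted p = 0.0368) beside the 11. The labels do not say whether shared numbers pair the samples. The correlations of same-numbered deviations were -0.243, 0.011, 0.004 and -0.332, and 0 of 4 PC61 samples correlated best with their own number. This gave no sign of pairing, but so few samples cannot exclude it. The block spends degrees of freedom, so the loss is not read as a weaker effect.

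Leaving out 1 sample gave 753 (without PC61 replicate 3) to 3754 genes (without PC61 replicate 2), 527 to 1986 higher, 226 to 1768 lower, 11 to 15 lists, 6 to 10 lists higher and 5 lists lower throughout. Of the 753 genes, 750 were among the 2679, in the same direction. Without PC61 replicate 4 and PBS replicate 4 together 1403 genes passed (920 higher, 483 lower), with 10 lists higher.

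With the melanocyte covariate 10 genes passed (4 higher, 6 lower), and 2225 at an unadjusted p under 0.05. Of the lists 13 passed as higher and 1, proliferation, as lower. The sign turned, with a call in 1 of the 2 fits, for the cytotoxic lymphocyte (0.668), interferon gamma response (0.157), chemokine (0.490) and melanocyte lists (0.061, by construction), and without a call in either for MHC class I (0.174), eosinophil and type 2 (-0.042), blood endothelium (0.092) and erythroid (0.137). An estimated correlation left 0 lists (0 higher, 0 lower), and fry 6 (4 higher, 2 lower). Foxp3 passed with 75th percentile scaling (-0.37, exact p = 0.0397) and had -0.38 to -0.23 with 1 sample left out; its exact p ran from 0.0397 to 0.179 over all alternatives. Apart from those stated, the cause was not tested. Of the single gene values, 0 turned with a call, 172 lost it and 23 gained one. Dim genes are limited by signal over background.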

Other observations

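The hair follicle, sebaceous gland, amino acid, neural crest and ribosome biogenesis lists were chosen after seeing the data, so their tests are no independent evidence. All 20 measured genes of a hair follicle and hair keratin list rose in PC61 (median 1.86, camera adjusted p = 4.64e-11 over 5 lists, and adjusted p = 0.185 with an estimated correlation). Among them were Shh, a secreted signal of the growing follicle (2.23), Hoxc13, a regulator of hair keratins (2.14), and the hair keratin gene Krt31 (2.23). In a sebaceous gland list 6 of 8 genes rose and 1 fell (median 2.83-fold, camera adjusted p = 0.00606, and adjusted p = 0.234 with an estimated correlation), with Elovl3 at 1.89 and Fads2 at -1.11.

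Genes of amino acid supply and the ATF4 stress response went both ways. Of 17 genes 8 fell and 3 rose, and the list did not pass camera (adjusted p = 0.0825). Trib3 (-1.69), Aldh1l2 (-1.51), Mthfd2 (-1.44) and Asns, asparagine synthetase (-0.95), fell, while Chac1 (1.75) and Slc7a11, the cystine transporter gene (1.23), rose. In a list of neural crest and embryonic genes 7 of 12 fell and 4 rose (camera adjusted p = 0.167), with Igf2bp3 at -2.00 and Eya1 at -1.99 against Tfap2b at 1.43. In a ribosome biogenesis list 1 of 11 genes fell, Nop58 (-0.75), and the list did not pass camera (adjusted p = 0.0815). With fry the amino acid, neural crest and ribosome biogenesis lists passed as lower (adjusted p = 0.00355, 0.0152 and 0.00523). With camera at an estimated correlation none of them passed (adjusted p = 0.185, 0.279 and 0.185).

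The pan T cell, cytotoxic lymphocyte and macrophage lists were fixed beforehand, but the melanocyte covariate was chosen after seeing the data. With it their medians were 0.71, 0.67 and 0.45 (camera adjusted p = 0.0113, 0.0257 and 0.00773). In the fit of all 9 arrays without it they were 0.12, -0.08 and 0.09 (camera adjusted p = 0.8795, 0.9147 and 0.5103). With an estimated correlation the adjusted p was 0.953 for each. The medians were 0.004, -0.26 and -0.07 without PC61 replicate 3, and none passed. Without PC61 replicate 4 alone the pan T cell median was 0.47 (adjusted p = 0.0723).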
